A study of Homo sapiens with 24 samples.

How the data were processed

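Total RNA of 2 human diffuse large B cell lymphoma lines was profiled on 24 Illumina bead arrays, 3 for each of 8 groups formed by cell line, treatment and time point. Per the labels, RNA was extracted with a column kit, passed an integrity check, and was amplified to biotinylated cRNA with the Ambion TotalPrep kit. The groups were taken from the labels, in which the short name ET was read as trabectedin because the treatment label of the same samples says so. The labels give no drug dose and do not say whether replicates were separate cultures.

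The authors deposited a table of probe intensity on a linear scale, neither background-subtracted nor scaled between arrays, with 47231 probes per array and no detection p-values. The authors also deposited a table of log2 values, quantile normalised. These deposited log2 values were checked against the intensities: they differed from quantile-normalised log2 intensities by at most 4.99e-09. The analysis began from the intensities. The probe table pairs 30113 probes with 1 gene symbol, 8 probes with several and 17110 with none, and only probes with 1 symbol were used. RefSeq gene names (the GRCh38.p14 release) served only to match older symbols and to tell which genes neighbour each other.

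Because detection p-values were missing, the background had to be measured in another way, chosen after the deposited table was seen to lack them. A set of 703 probes for gene families silent in B cells, such as olfactory receptors, keratin-associated proteins and taste receptors, stood in for negative controls. A probe's detection p was the share of these probes that were at least as bright on the same array. Intensities were corrected with the normexp model of limma (function nec), given an offset of 16, log2-transformed and quantile normalised over all 24 arrays. Probes with a detection p under 0.01 on at least 3 arrays were kept, which left 12564 probes for 9550 genes. For the 2430 genes with more than 1 tested probe, the probe with the highest mean was taken. The text names the genes whose other probes moved the other way.

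Depth on an array is signal over background: on every array the median intensity of the silent-family probes lay below that of all probes. With 3 arrays per group, the number of arrays limits the precision. Where all 3 arrays of one group were in the background, a fold is given as a lower bound, computed against the lowest normalised value among detected probes on each of those arrays. No fold is given where both groups were in the background. Where only 1 or 2 arrays of a group were in the background, the fitted change is given, and its size rests partly on such values, as for AFF3 and JUN in OCI-Ly7 and CD14 in U2932 at 8 h.

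R 4.3.3 with limma 3.58.1 fitted 1 mean per group and 1 spread per gene over all 24 arrays, moderated by empirical Bayes. The comparisons are 4 trabectedin effects (trabectedin minus DMSO per line and time), the differences of these effects between lines and between times, the change of the DMSO arrays over time, and the difference between the lines in DMSO, 11 in all. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors from limma with n = 3 per group, and errors of array measures are SD. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

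Gene lists, 31 in all, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The 29 lists with at least 5 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Each call was repeated with an estimated correlation and with fry. Members that rose or fell were counted over all genes tested and with p adjusted over the list alone. The named genes of each trabectedin effect are the 10 with the highest and the 10 with the lowest log2 change among called genes. These had to be detected on all 3 arrays of a group and to have every treated array on one side of every DMSO array. The rule adds up to 4 called members of each list, 2 at each end. For differences between effects it takes the 5 highest and 5 lowest, for DMSO over time the 3 highest and 3 lowest, and for the lines in DMSO the members of the lymphoma subtype lists. Sex-specific genes and unnamed loci were passed over.

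The pipeline was tested on simulated data: in 6 simulated sets, 200 genes were changed among 9180 to 9358. With the spread shared over all arrays, 61.2%, 94.5% and 99.8% of genes changed 1.5-fold, 2-fold and 4-fold were called in simulated U2932 at 8 h, and 65.2%, 93.5% and 100% in simulated OCI-Ly7 at 24 h. Unchanged genes made up 2.58% of the calls in the U2932 simulation but 12.9% in the OCI-Ly7 simulation. With the spread taken only from the arrays compared, these shares were 4.98% and 5.08%. In the simulation the shared spread was therefore too small for OCI-Ly7. The simulated noise had the same spread per probe in both lines, so it cannot show whether real OCI-Ly7 arrays vary more. Real replicates correlated at r down to 0.970 in OCI-Ly7 and 0.991 in U2932. The simulated sets also changed far fewer genes than were called in the real effects. Counts from the arrays compared alone stand beside the OCI-Ly7 counts. Simulated rising lists were called in 6 of 6 sets, and 1 of 300 random lists was called.

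The arrays lay on 3 chips. All 12 U2932 arrays shared chip 1, chip 2 held the 6 OCI-Ly7 DMSO arrays and the 3 OCI-Ly7 arrays after 8 h of trabectedin, and chip 3 held only the 3 OCI-Ly7 arrays after 24 h of trabectedin. In OCI-Ly7 at 24 h, chip and treatment cannot be told apart, and neither can chip and cell line. Replicate numbers were checked for pairing by correlating residuals: not every numbered pair reached a correlation of 0.1 in any comparison, so samples were not treated as pairs. Alternatives covered normalisation (quantile within each line, median scaling, cyclic loess), background correction, the offset, the deposited values, detection filters, the mean of a gene's probes, the arrays in the fit, a replicate block, chip position, the variance prior and leaving out each array. Gene length was not examined, since the gene table serves only for names and neighbours.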

Results

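The series asked how trabectedin changes gene expression in diffuse large B cell lymphoma. Trabectedin is a chemotherapy drug that binds the minor groove of DNA. U2932 is an established line usually assigned to the activated B cell-like subtype, and OCI-Ly7 one usually assigned to the germinal centre B cell-like subtype. Each line was exposed to trabectedin or to the solvent DMSO for 8 h or 24 h, with 3 arrays in each of the 8 groups and 24 arrays in all.

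Trabectedin arrays of U2932 were dimmer than their DMSO arrays. Mean probe intensity in U2932 was 460 ± 5.54 (SD, n = 3) after 8 h of trabectedin against 539 ± 17.8 in DMSO, and 365 ± 21.6 against 543 ± 11.8 at 24 h. In OCI-Ly7 it was 365 ± 53.7 against 326 ± 19.5 at 8 h and 235 ± 45.0 against 366 ± 83.3 at 24 h. Exact permutation p-values for these contrasts, two-sided, were 0.1, 0.1, 0.4 and 0.1, and 0.1 is the smallest that 3 against 3 arrays allow. U2932 had 11713 ± 350 (SD, n = 3) detected probes per array after 8 h of trabectedin against 12871 ± 509 in DMSO, and 10496 ± 1128 against 13598 ± 403 at 24 h. OCI-Ly7 had 12510 ± 904 against 13283 ± 290 at 8 h and 12692 ± 405 against 12866 ± 673 at 24 h. Exact permutation p-values, two-sided, were 0.1, 0.1, 0.3 and 0.8. At a detection p under 0.05 in place of 0.01, OCI-Ly7 had 16997 ± 437 against 18407 ± 138 at 8 h and 16661 ± 464 against 18114 ± 313 at 24 h (SD, n = 3; exact permutation p = 0.1 for both), so its contrast depends on the threshold. Replicates correlated across probes at r between 0.970 and 0.998, lowest among the OCI-Ly7 DMSO arrays of 24 h, where replicate 3 had a mean intensity of 270.

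**Figure D1:**
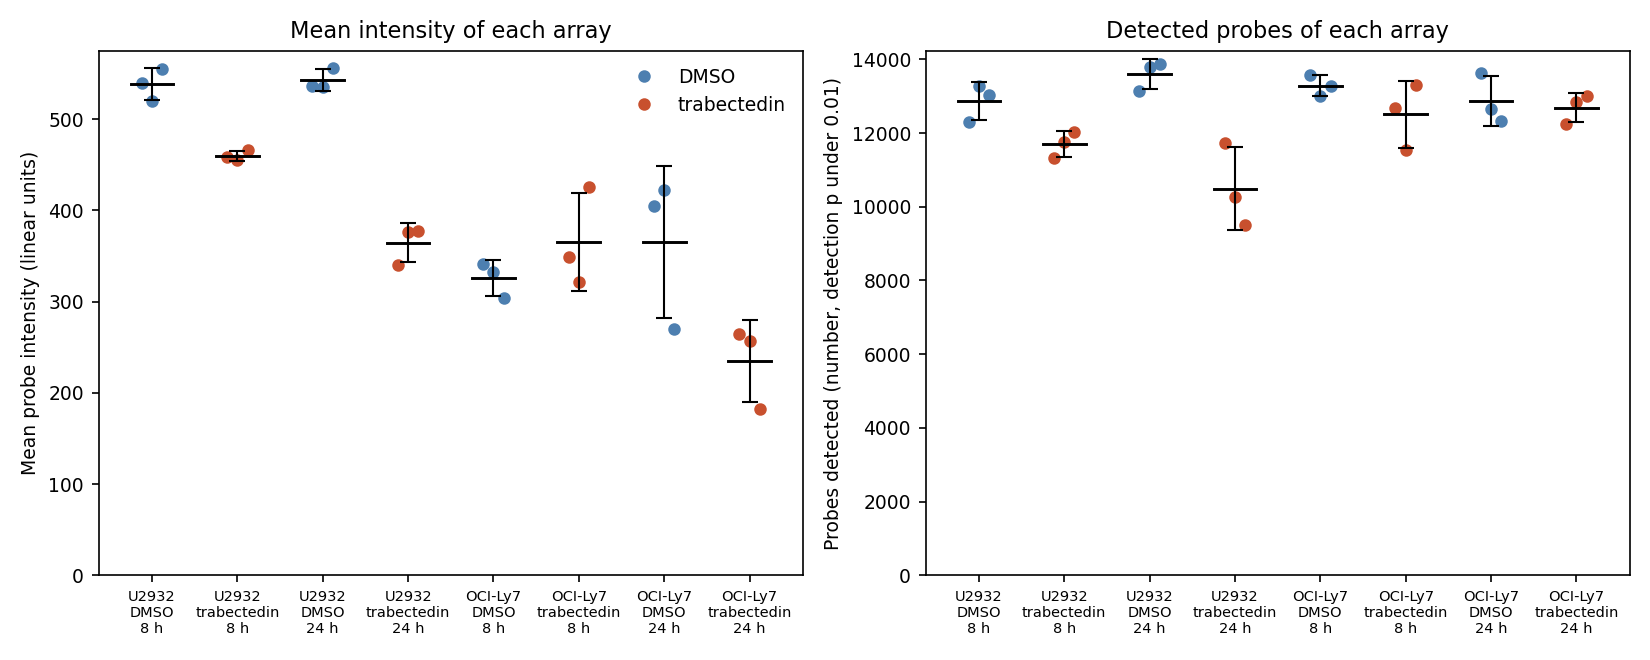
Mean probe intensity (left, linear units) and number of detected probes (right) of each array by group; points are arrays, lines are group means and bars are 1 SD (n = 3). Treated U2932 arrays lie below all DMSO arrays of the same time on both axes, down to means of 365 and 10496 at 24 h.

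In U2932 at 8 h, ELMO1, an activator of Rac signalling, was at least 13.3-fold lower after trabectedin than in DMSO, and DDX10, an RNA helicase, at least 17.1-fold lower; both were in the background on all 3 treated arrays. PLCL2, STAMBPL1, FOXN3, CUX1, ARHGEF3, ZBTB7C, POLR3B, a subunit of RNA polymerase III, and PHLPP1, a phosphatase, were lower by at least 15.3-fold, 13.7-fold, 13.8-fold, 14.3-fold, 12.7-fold, 8.53-fold, 7.68-fold and 6.56-fold. Growth hormone (GH1) was in the background in DMSO and at least 5.73-fold higher after treatment, and the retinoic acid-binding protein gene CRABP2 at least 11.2-fold higher. CPLX4, a complexin of synapses, TSPOAP1, LSMEM1, IDI2, COXFA4L3 and the non-coding RNA BCAR4 rose by at least 9.96-fold, 9.51-fold, 9.49-fold, 9.17-fold, 7.12-fold and 5.28-fold. CD14, a receptor for bacterial lipopolysaccharide, rose by 3.74 ± 0.19 on the log2 scale (n = 3, adjusted p = 1.12e-13). The signal of the probe for 18S ribosomal RNA (RNA18SN5) rose by 4.97 ± 0.55 (adjusted p = 3.64e-08). Whether this probe, or those of other ribosomal, small non-coding and histone RNAs named below, read the mature forms was not measured.

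Among the gene lists in U2932 at 8 h, immediate early and short-lived transcripts rose together. Of 29 tested members 23 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 4.08e-05, adjusted p = 0.268 with an estimated correlation). JUN, a subunit of AP-1, was at least 3.96-fold higher, and JUNB rose by 2.51 ± 0.18. Replication-dependent histone genes rose in 14 of 15 tested members, 14 also adjusted over the list alone (adjusted p = 0.000339, adjusted p = 0.335 with an estimated correlation). H2AC17 and H2BC21 were at least 4.86-fold and 4.36-fold higher, while H4C3 fell by 0.39 ± 0.12. Mitosis genes fell in 26 of 37 members and rose in 2 (27 and 2 adjusted over the list alone; adjusted p = 0.00180, adjusted p = 0.335 with an estimated correlation). The spindle checkpoint kinase TTK fell by 2.57 ± 0.13 and the centromere motor CENPE by 2.00 ± 0.13. BIRC5 (survivin) rose by 1.65 ± 0.12; KIF23 rose by 0.68 ± 0.12, but its other probe moved the other way.

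B cell receptor signalling genes fell in 15 of 25 members and rose in 3 in U2932 at 8 h, with the same counts adjusted over the list alone (adjusted p = 0.0305, adjusted p = 0.335 with an estimated correlation). LYN, a proximal kinase of the receptor, fell by 2.52 ± 0.16, and MALT1, a protease that signals to NF-kB, by 2.32 ± 0.18. BCL10 rose by 0.71 ± 0.16. The myeloid marker list has 5 tested members, of which 4 rose (5 adjusted over the list alone; adjusted p = 0.0139, adjusted p = 0.268 with an estimated correlation). They include CD14 and FCER1G, at least 1.44-fold higher. Of the 5 members, 1 was in the background in both groups, so its change was not measurable, and 3 were in the background in 1 group. The list has 10 members, and the others did not pass the detection filter or were not matched. A member in the background on all DMSO arrays was tested only if treated arrays detected it. The filter thus favours rises in this list, and its call may be partly set by the filter. The list medians were 1.02 for immediate early transcripts, 1.22 for histones, -0.76 for mitosis, -0.73 for B cell receptor signalling and 1.71 for myeloid markers. Without background correction they were 0.67, 0.61, -0.58, -0.36 and 0.66, and under median scaling 0.60, 0.75, -1.38, -1.11 and 1.62. With genes in the background set at their bound, they were 1.10, 1.00, -0.76, -0.44 and 0.50.

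In all, 3122 genes were higher and 3554 lower in U2932 at 8 h, of 9550 tested, and 1000 and 1835 of them changed by at least 1 on the log2 scale (407 and 953 without background correction, 395 and 3241 under median scaling). P-values here measure the spread between these arrays. The labels do not say whether replicates were separate cultures, so the p-values may not cover the spread between separate experiments. Under median scaling, which left the median of all genes at -0.49, 884 genes were higher and 4630 lower. Median scaling aligns the median of all probes, most of them undetected, so differences in array brightness stay in the expressed genes. Among genes detected on every array compared, 2068 were lower.

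In U2932 at 24 h, TNS3, a focal adhesion protein, was at least 15.6-fold lower after trabectedin, PVRIG, an inhibitory immune receptor, at least 16.8-fold lower, and CDK6, the G1 kinase, at least 10.3-fold lower. STAMBPL1, ARHGEF3, DDX10, FOXN3, COP1, a ubiquitin ligase, SCAMP1 and OSBPL10 were lower by at least 9.85-fold, 11.2-fold, 12.4-fold, 8.05-fold, 11.6-fold, 9.80-fold and 11.5-fold. GH1, AMH (anti-Müllerian hormone), GGT1 and apolipoprotein E (APOE) were higher by at least 13.8-fold, 11.5-fold, 10.8-fold and 10.1-fold. RNA18SN5 rose by 7.27 ± 0.55, CD14 by 4.78 ± 0.19, and the small nucleolar RNAs SNORD110, SNORD46, SNORD3C and SNORD3D by 5.02 ± 0.14, 4.95 ± 0.22, 4.78 ± 0.25 and 4.61 ± 0.26.

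Germinal centre B cell-like lymphoma markers fell in all 13 tested members in U2932 at 24 h, 13 also adjusted over the list alone (adjusted p = 0.00127, adjusted p = 0.273 with an estimated correlation). MME (CD10) was at least 2.94-fold lower, and STAP1 fell by 3.24 ± 0.25. The fall was not particular to germinal centre markers. Activated B cell-like markers, a list that was not called, had a median of -0.45 in U2932 at 8 h and -1.23 at 24 h. With genes in the background at their bound, these medians were -0.25 and -0.93. B cell receptor signalling genes fell in 19 of 25 members and rose in 3, with the same counts adjusted over the list alone (adjusted p = 0.00567, adjusted p = 0.273 with an estimated correlation). LYN fell by 4.52 ± 0.16 and the kinase SYK by 3.64 ± 0.12. Mitosis genes fell in 27 of 37 members and rose in 2, counts that held adjusted over the list alone (adjusted p = 0.00251, adjusted p = 0.437 with an estimated correlation). DLGAP5, a spindle assembly factor, fell by 3.34 ± 0.13, ECT2 was at least 5.50-fold lower, and BIRC5 rose by 2.03 ± 0.12.

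Immediate early transcripts in U2932 at 24 h rose in 21 of 29 members and fell in 3, the same adjusted over the list alone (adjusted p = 0.000165, adjusted p = 0.273 with an estimated correlation). JUN was at least 12.5-fold higher, and the stress transcription factor ATF3 rose by 4.50 ± 0.27. Histone genes rose in 14 of 15 members, 14 also adjusted over the list alone (adjusted p = 0.000299, adjusted p = 0.342 with an estimated correlation). H2BC21 was at least 12.1-fold higher, H2AC17 rose by 3.54 ± 0.15, and H4C3 fell by 1.52 ± 0.12. Zinc finger genes rose in 149 of 277 members and fell in 70, the same adjusted over the list alone (adjusted p = 0.000478, adjusted p = 0.273 with an estimated correlation), and under median scaling 54 rose and 130 fell. ZNF84 rose by 3.98 ± 0.15 and ZNF317 by 3.31 ± 0.16, while ZNF215 and ZNF532 were at least 8.29-fold and 6.73-fold lower. Myeloid markers were called higher in 5 of 5 members, 5 adjusted over the list alone (adjusted p = 0.0470, adjusted p = 0.273 with an estimated correlation). Of these 5, 1 was in the background in both groups, so its rise was not measurable, and 2 were in the background in 1 group. As at 8 h, the detection filter favours rises in this list.

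List medians in U2932 at 24 h were -1.96 for germinal centre markers, -1.53 for B cell receptor signalling, -1.09 for mitosis, 1.32 for immediate early transcripts, 1.91 for histones, 0.75 for myeloid markers and 0.44 for zinc finger genes. Without background correction they were -1.55, -0.88, -0.97, 1.10, 1.23, 0.33 and 0.29. Under median scaling the first 6 were -3.16, -2.21, -1.88, 0.73, 1.22 and 0.65, and the zinc finger median was -0.36, 0.69 above that of all genes. With genes in the background at their bound, the medians were -1.71, -0.77, -0.96, 1.39, 1.74, 0.63 and 0.52. In all, 3401 genes were higher and 4348 lower, and 1813 and 2974 changed by at least 1 on the log2 scale (1113 and 1784 without background correction, 554 and 4868 under median scaling). Under median scaling 1110 were higher and 6002 lower, with the median of all genes at -1.04. Among genes detected on every array compared, 1856 were lower.

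**Figure D2:**
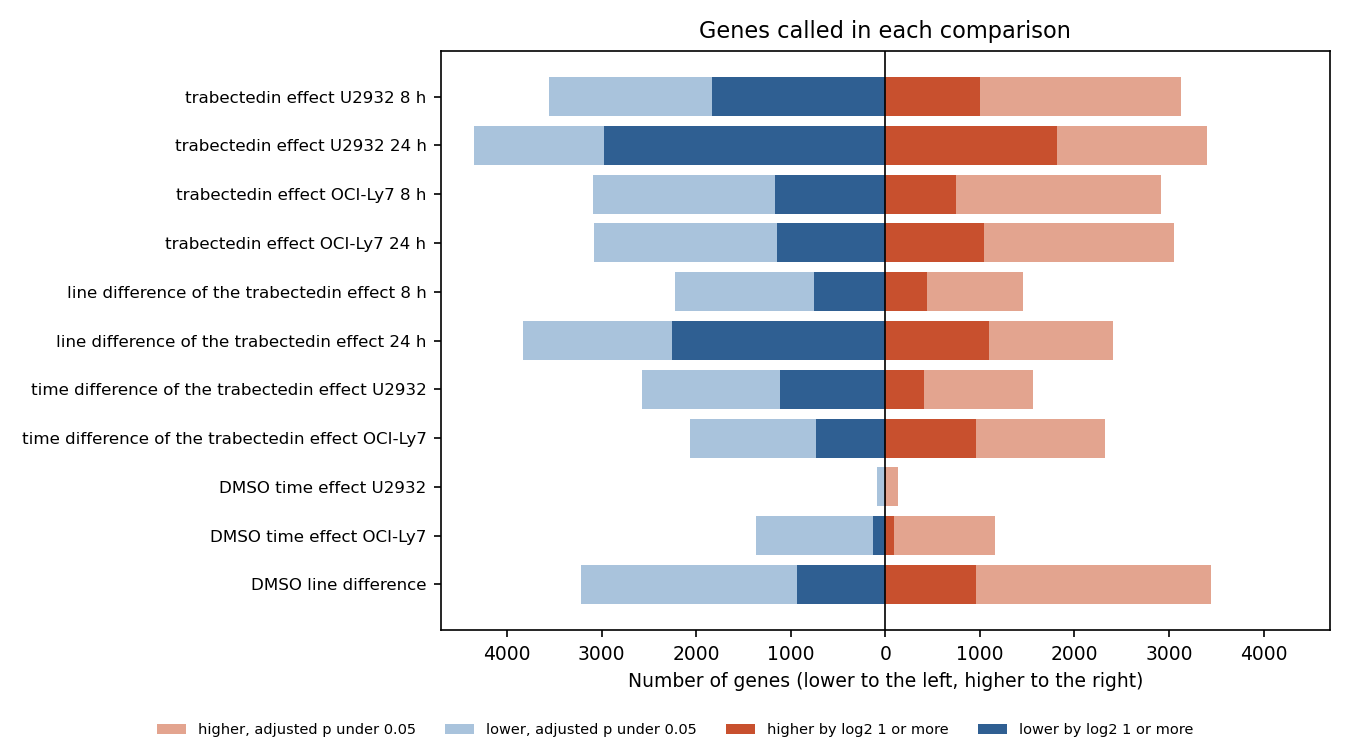
Number of genes called in each of 11 comparisons (horizontal axis, lower to the left and higher to the right); pale bars are all calls at an adjusted p under 0.05 and dark bars those with a log2 change of at least 1, which are fewer in each comparison without background correction. The longest bar to the left belongs to U2932 at 24 h (4348 genes lower) and the longest to the right to the lines in DMSO (3441 higher).

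In OCI-Ly7 at 8 h, AFF3, a transcription elongation factor expressed in lymphoid cells, fell by 4.17 ± 0.28 with trabectedin (n = 3, adjusted p = 4.91e-11), and the phosphatase gene UBASH3B by 3.71 ± 0.24. CMIP (-3.50 ± 0.20), POLR3B (-3.44 ± 0.19), the poly(A) ribonuclease gene PARN (-3.37 ± 0.23) and the fatty acid synthesis gene ACACA (-3.24 ± 0.17) fell too, and CUX2 was at least 4.18-fold lower, in the background after treatment. So did TNS3 (-3.12 ± 0.17), RAPGEF5 (-3.09 ± 0.25) and the pseudogene CRSP8P (-3.13 ± 0.15). TSPOAP1, GH1 and CRABP2, in the background in DMSO, were higher by at least 13.9-fold, 7.67-fold and 5.05-fold, and SCG5, CHN1, CEL and GH2 by at least 5.66-fold, 5.18-fold, 3.09-fold and 3.06-fold. ATP5MK rose by 3.97 ± 0.10, RNA18SN5 by 3.78 ± 0.55 and 5S ribosomal RNA (RNA5S9) by 2.77 ± 0.25.

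Mitosis genes fell in 25 of 37 members and rose in 5 in OCI-Ly7 at 8 h, 26 and 5 adjusted over the list alone (adjusted p = 0.00142, adjusted p = 0.504 with an estimated correlation). CENPF fell by 1.43 ± 0.15 and CENPA, the centromeric histone, by 1.59 ± 0.14, though the other CENPA probe moved the other way. Germinal centre markers fell in 10 of 13 members and rose in 0, the same adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.504 with an estimated correlation). SSBP2 fell by 2.76 ± 0.18 and STAP1 by 1.41 ± 0.25. B cell receptor signalling genes fell in 14 of 25 members and rose in 3, the same adjusted over the list alone (adjusted p = 0.0239, adjusted p = 0.504 with an estimated correlation). MALT1 fell by 1.81 ± 0.18 and the phospholipase gene PLCG2 by 1.43 ± 0.16, while BCL10 rose by 0.65 ± 0.16. The medians of these 3 lists were -0.65, -0.88 and -0.54, and -0.65, -0.75 and -0.37 with genes in the background at their bound. Without background correction they were -0.53, -0.56 and -0.35, and under median scaling -0.43, -0.97 and -0.43.

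Across OCI-Ly7 at 8 h, 2913 genes were higher and 3096 lower, and 748 and 1172 changed by at least 1 on the log2 scale (263 and 538 without background correction). With the spread taken from the 6 arrays compared, the counts were 2829 and 3045. Under median scaling they were 1996 and 2385, and 8 lists were called in place of 3.

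In OCI-Ly7 at 24 h, AFF3 fell by 4.53 ± 0.28 with trabectedin, and EBF1, a transcription factor of B cell identity, was at least 5.79-fold lower. RSRC1 was at least 12.7-fold lower, and ELMO1 at least 9.23-fold lower by the main probe, with 1 of its 3 probes moving the other way. ZNF385B (-4.27 ± 0.21), ARHGAP15 (-3.89 ± 0.14), LPP (-3.86 ± 0.24), FAF1 (-3.82 ± 0.23), the mTOR inhibitor gene DEPTOR (-3.82 ± 0.18) and OSBPL10 (-3.78 ± 0.17) fell as well. JUN rose by 3.88 ± 0.27, the muscle enolase gene ENO3 by 3.83 ± 0.19, RNA5S9 by 5.11 ± 0.25, RPPH1, the RNA of RNase P, by 3.61 ± 0.14, RNU4ATAC, a minor spliceosome RNA, by 3.58 ± 0.15 and SNORD3C by 3.12 ± 0.25. SNORD84, GH1, CD14 and KLHL15 were higher by at least 10.05-fold, 8.65-fold, 8.30-fold and 7.60-fold.

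Immediate early transcripts rose in 21 of 29 members and fell in 2 in OCI-Ly7 at 24 h, 22 and 2 adjusted over the list alone (adjusted p = 6.44e-05, adjusted p = 0.254 with an estimated correlation). FOSB, another AP-1 subunit, rose by 3.01 ± 0.23, while MYC fell by 0.77 ± 0.11. Zinc finger genes rose in 157 of 277 members and fell in 33, 160 and 34 adjusted over the list alone (adjusted p = 2.05e-05, adjusted p = 0.160 with an estimated correlation), and under median scaling 25 rose and 99 fell. ZNF223 rose by 2.21 ± 0.12 and ZNF84 by 2.11 ± 0.15. Histone genes rose in 11 of 15 members and fell in 1, the same adjusted over the list alone (adjusted p = 0.00666, adjusted p = 0.519 with an estimated correlation). H2AC17 rose by 2.33 ± 0.15 and H2BC5 by 2.15 ± 0.13. Interferon response genes rose in 10 of 20 members and fell in 2, the same adjusted over the list alone (adjusted p = 0.0280, adjusted p = 0.160 with an estimated correlation), and under median scaling 3 rose and 7 fell. IRF7, a regulator of interferon genes, rose by 2.75 ± 0.16, and TRIM22 fell by 0.64 ± 0.11.

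B cell receptor signalling genes fell in 17 of 25 members and rose in 3 in OCI-Ly7 at 24 h, the same adjusted over the list alone (adjusted p = 0.00250, adjusted p = 0.198 with an estimated correlation). PRKCB, the protein kinase C of B cells, fell by 3.61 ± 0.17 and LYN by 1.89 ± 0.16. Germinal centre markers fell in 9 of 13 members, 9 also adjusted over the list alone (adjusted p = 0.00459, adjusted p = 0.393 with an estimated correlation). RGS13 fell by 2.33 ± 0.16 and SSBP2 by 2.16 ± 0.18. Activated B cell-like markers, not called in OCI-Ly7 either, had medians of -0.36 at 8 h and -0.37 at 24 h. Of 37 mitosis genes 15 rose and 9 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.570); under median scaling 0 rose and 20 fell. BIRC5 rose by 1.45 ± 0.12 and KIF2C by 1.19 ± 0.17, neither called under median scaling, while KIF11 fell by 0.92 ± 0.14. These 3 treated arrays had the lowest mean intensity of the groups, 235 ± 45.0 (SD, n = 3), and a chip of their own.

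List medians in OCI-Ly7 at 24 h were 0.88 for immediate early transcripts, 0.45 for zinc finger genes, 0.85 for histones, 0.42 for interferon response, -0.89 for B cell receptor signalling, -0.81 for germinal centre markers and 0.05 for mitosis. With genes in the background at their bound, the medians of the 6 called lists were 0.87, 0.39, 0.43, 0.31, -0.67 and -0.81. Under median scaling the 7 medians were 0.10, -0.32, 0.25, -0.28, -1.33, -1.70 and -0.86, with zinc finger and interferon genes 0.43 and 0.47 above the median of all genes and mitosis 0.11 below it. Without background correction they were 0.57, 0.24, 0.53, 0.21, -0.52, -0.52 and 0.04. In all, 3051 genes were higher and 3085 lower, with 1041 and 1147 changed by at least 1 on the log2 scale (494 and 525 without background correction, 141 and 3643 under median scaling). With the spread taken from the 6 arrays compared, 2219 were higher and 2357 lower. Under median scaling 461 were higher and 5902 lower, with the median of all genes at -0.75, and chip and treatment cannot be told apart.

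**Figure D3:**
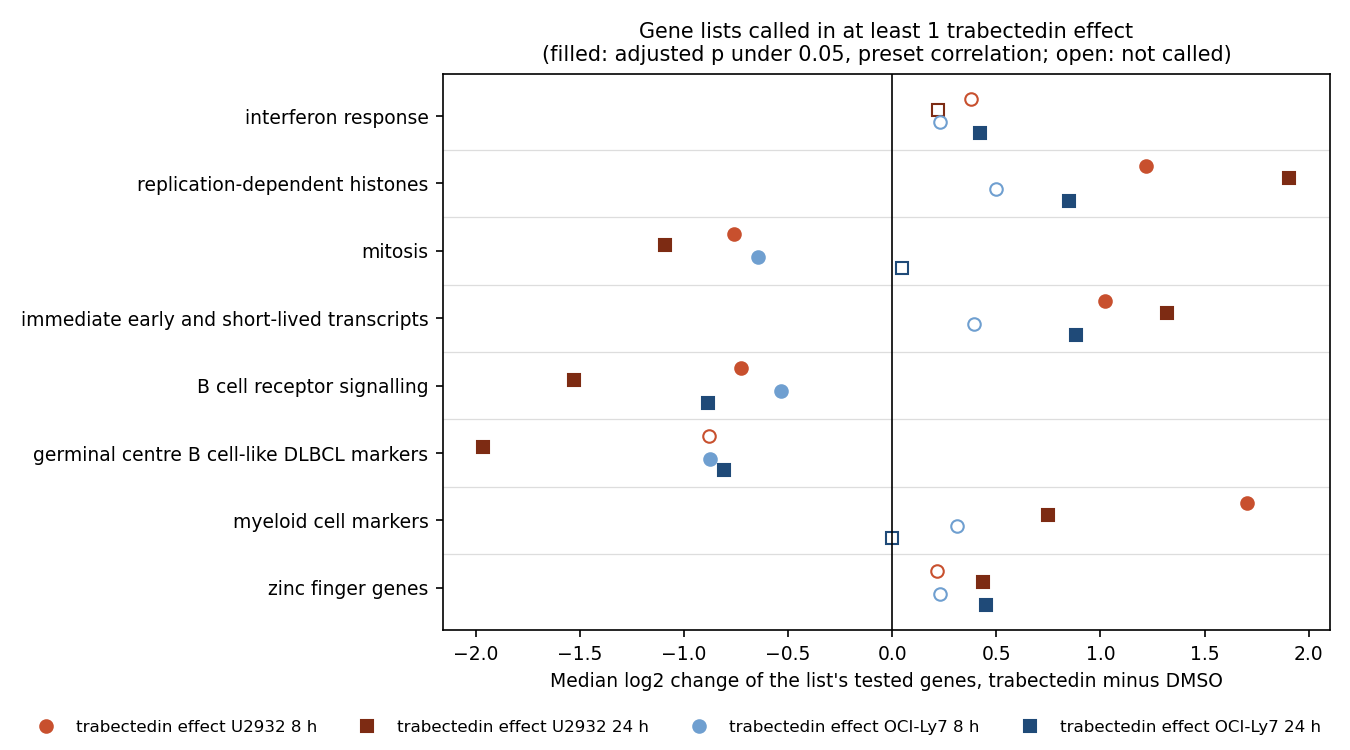
Median log2 change (horizontal axis, trabectedin minus DMSO) of the 8 gene lists called in at least 1 trabectedin effect; circles are 8 h, squares 24 h, and filled symbols are calls at the preset correlation. Mitosis genes lie at -1.09 in U2932 at 24 h and at 0.05 in OCI-Ly7 at 24 h; under median scaling the OCI-Ly7 mitosis median at 24 h (-0.86), the zinc finger medians of U2932 at both times and of OCI-Ly7 at 24 h, and the interferon medians of both lines at 24 h lie below 0.

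Many genes moved the same way in both lines. At 8 h, 2015 genes were higher in both lines, where independent calls would give 952, and 2442 lower in both, against 1152. TSPOAP1, GH1 and CRABP2 were among the named genes that rose in both, and POLR3B among those that fell in both. At 24 h, 2122 were higher in both, against 1087, and 2487 lower in both, against 1405. Calls in opposite directions numbered 103 and 146 at 8 h (higher in U2932, then lower in U2932) and 202 and 391 at 24 h. Across genes, which are not independent replicates, the log2 changes of the lines correlated at r = 0.777 at 8 h and 0.689 at 24 h, and the lines share no control arrays. Under median scaling the genes higher in both numbered 593 at 8 h and 290 at 24 h, and those lower in both 2160 and 4748.

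**Figure D4:**
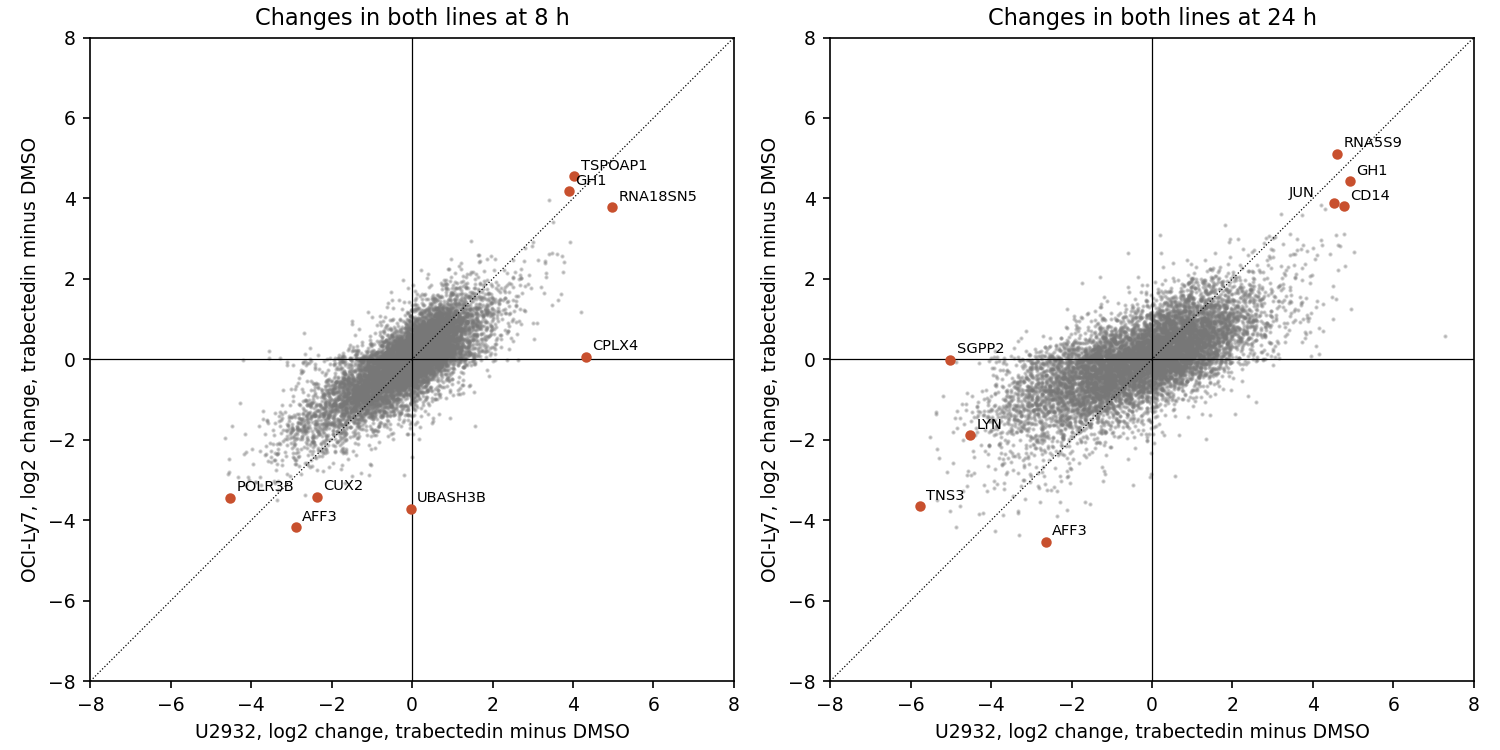
Log2 change with trabectedin in U2932 (horizontal axis) against OCI-Ly7 (vertical axis) for each gene tested at 8 h (left) and 24 h (right); the dotted line marks equal change and some named genes are in red. The cloud runs along the diagonal (r = 0.777 and 0.689 across genes), with CPLX4, UBASH3B and SGPP2 on an axis, since each is in the background of 1 line.

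The response differed between the lines in many genes, as tested by the interaction of line and treatment. SORBS2, an adaptor of the actin skeleton, rose out of the background in U2932 and fell into it in OCI-Ly7 at 8 h (n = 3 per group, adjusted p = 8.21e-11 for the difference). CPLX4, in the background in DMSO in both lines, rose in U2932 and stayed in the background in OCI-Ly7. Others with large differences were expressed in only 1 line in DMSO: UBASH3B fell in OCI-Ly7 and was in the background in U2932. ZBTB7C, SPIRE1 and WWC1 fell in U2932 and were in the background in OCI-Ly7. At 24 h, ZNF215 was lower in U2932 than its DMSO arrays by at least 8.29-fold, and in OCI-Ly7 its log2 change was -0.07 ± 0.14 (adjusted p = 3.80e-14 for the difference). HPCAL1, a neuronal calcium sensor, fell into the background in U2932 and was detected on all 24 h arrays of OCI-Ly7, and uridine phosphorylase (UPP1) rose in U2932 and was in the background in OCI-Ly7.

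Mitosis genes differed between the lines at 24 h: the change was lower in U2932 for 31 of 37 and higher for 1 (32 and 1 adjusted over the list alone), with a median difference of -1.06 and -1.27 under median scaling (adjusted p = 8.07e-06, adjusted p = 0.469 with an estimated correlation). TTK fell by 2.30 ± 0.13 in U2932 at 24 h, and in OCI-Ly7 its log2 change was 0.05 ± 0.13. NF-kB targets were lower in the U2932 response in 14 of 20 members and higher in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.0211, adjusted p = 0.469 with an estimated correlation), and NFKB1 fell in both lines. Of the 20 NF-kB targets at 24 h, 7 were in the background in 1 group in U2932 and 5 in both groups in OCI-Ly7. With such genes at their bound, the NF-kB median was 0 in U2932 and 0.30 in OCI-Ly7, against -0.50 and 0.21. ATF4 target genes were higher in the U2932 response, 12 of 20 against 1, the same adjusted over the list alone (adjusted p = 0.00454, adjusted p = 0.469 with an estimated correlation). At 8 h, 9 ATF4 genes were higher and 1 lower (9 and 3 adjusted over the list alone; adjusted p = 0.0172, adjusted p = 0.389 with an estimated correlation), with a median of 0.41 that was -0.21 under median scaling.

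In all, 1451 genes differed upward in U2932 and 2223 downward at 8 h, 336 and 598 with chip position as a covariate, and 2405 and 3837 at 24 h. With the spread from the arrays compared, the counts were 1817 and 2587 at 8 h and 2143 and 3550 at 24 h. Under median scaling they were 300 and 3637 at 8 h (median of all genes -0.59) and 1502 and 3396 at 24 h (median -0.31). At 8 h treated arrays took early chip positions in U2932 and late ones in OCI-Ly7, so a trend along the chip would enter this difference. The covariate also widens the standard errors of this difference by design, so the lower counts do not show such a trend. Line and chip cannot be told apart.

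The response also changed with time, as tested by the interaction of time and treatment. In U2932, IKZF3 (Aiolos), a B cell transcription factor, rose by 2.07 ± 0.15 at 8 h and was in the background on the treated arrays at 24 h (adjusted p = 3.94e-10 for the difference). The gap junction gene GJB2 was above the background only after 24 h of trabectedin. MEX3B, an RNA-binding protein detected on 1 of the 6 DMSO arrays, was higher on the treated arrays at 24 h than at 8 h. Relative to DMSO, germinal centre markers were lower at 24 h than at 8 h in 11 of 13 members (12 adjusted over the list alone; adjusted p = 6.23e-05, adjusted p = 0.174 with an estimated correlation). NF-kB targets, with a median of 0.19 at 8 h (-0.40 under median scaling), were lower at 24 h in 12 of 20 and higher in 0 (14 and 1 adjusted over the list alone; adjusted p = 0.00272, adjusted p = 0.243 with an estimated correlation).

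In OCI-Ly7, mitosis genes were higher at 24 h than at 8 h relative to DMSO in 24 of 37 members and lower in 0 (25 and 0 adjusted over the list alone; adjusted p = 3.28e-06, adjusted p = 0.377 with an estimated correlation), with a median difference of 0.52 that was -0.40 under median scaling, 0.29 above all genes. ENO3 and the autophagy kinase gene ULK1 rose later, with differences of 3.11 ± 0.27 and 2.84 ± 0.29, and PRKCB fell later, with a difference of -3.24 ± 0.24. Cytokine and chemokine genes were higher at 24 h in 7 of 11 members and lower in 1, the same adjusted over the list alone (adjusted p = 0.0431, adjusted p = 0.377 with an estimated correlation). Across genes the changes at 8 h and 24 h correlated at r = 0.909 in U2932 and 0.608 in OCI-Ly7. In OCI-Ly7 only the treated 24 h arrays lie on a chip of their own, so chip and treatment cannot be told apart there.

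In U2932, 1562 genes differed upward with time and 2574 downward, and in OCI-Ly7 2319 and 2068 (1463 and 1254 with chip position as a covariate); with the spread from the arrays compared, OCI-Ly7 gave 1687 and 1434. Under median scaling the counts were 221 and 2798 in U2932 (median of all genes -0.41) and 163 and 4379 in OCI-Ly7 (median -0.69).

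**Figure D5:**
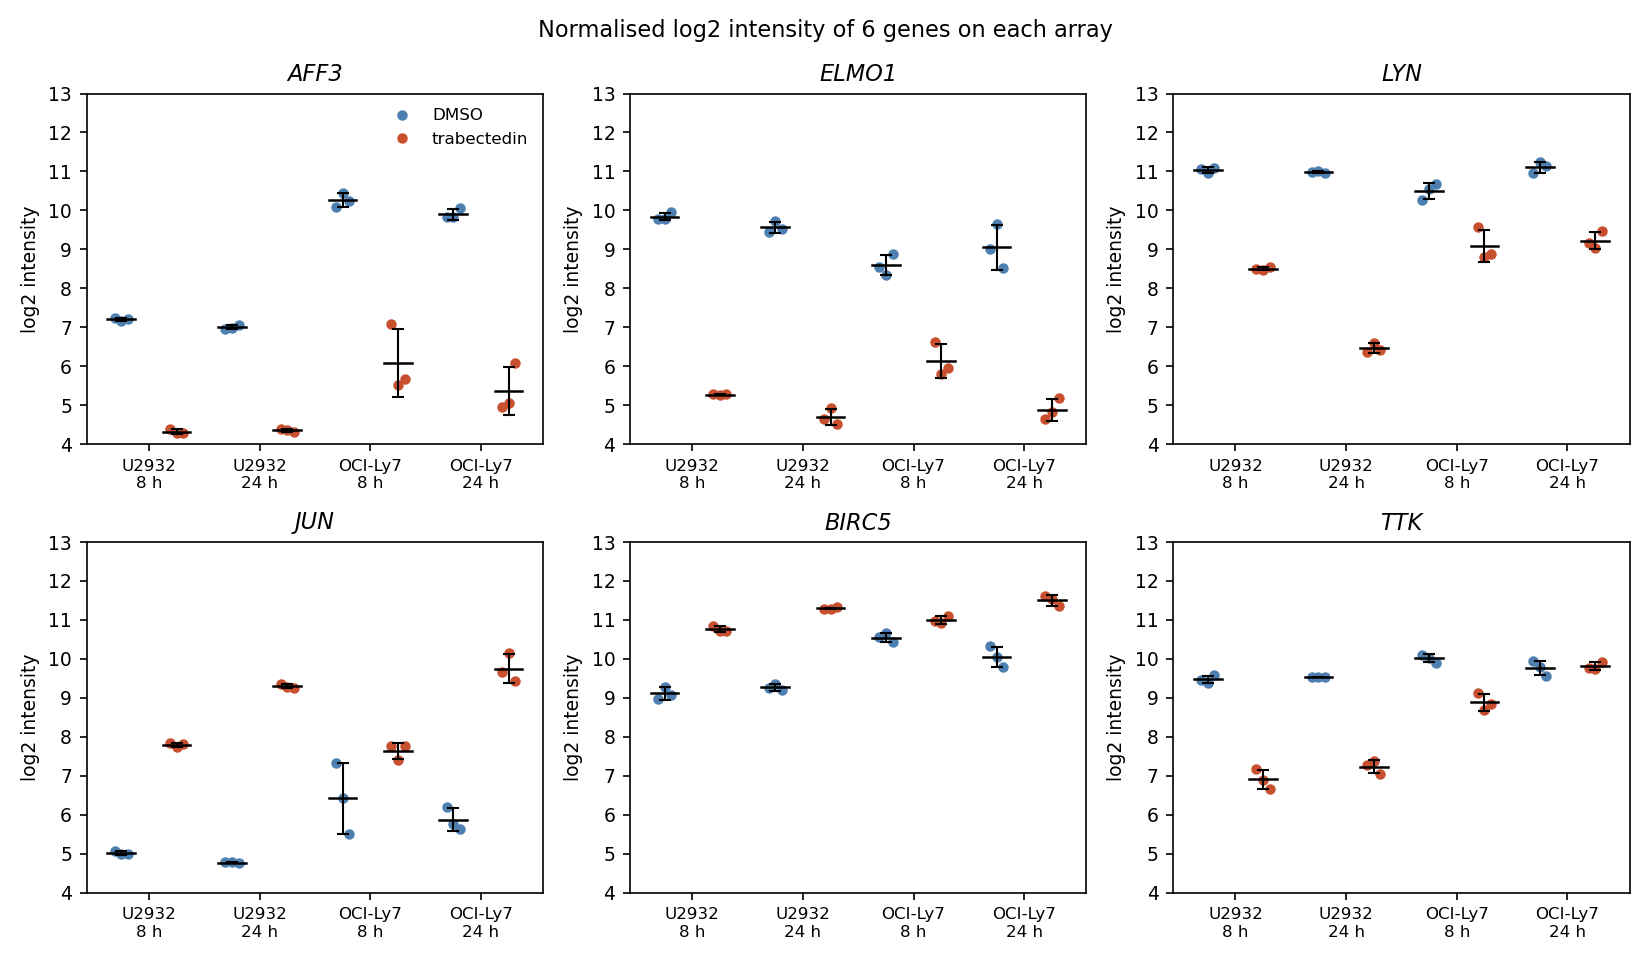
Normalised log2 intensity (vertical axis) of AFF3, ELMO1, LYN, JUN, BIRC5 and TTK on each array by line and time; points are arrays, lines are group means and bars are 1 SD (n = 3). LYN fell by 4.52 in U2932 and 1.89 in OCI-Ly7 at 24 h, and TTK by 2.30 in U2932, with a change of 0.05 in OCI-Ly7.

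Between 8 h and 24 h in DMSO alone in U2932, the nuclear lamina gene LMNB1 rose by 1.44 ± 0.18, TAF15 by 1.36 ± 0.13 and CIP2A by 1.26 ± 0.20, while the adhesion protein gene ZYX fell by 1.38 ± 0.23, AMY1A by 1.16 ± 0.11 and ADAP2 by 1.15 ± 0.14. Mitosis genes had a median of 0.21, with 2 of 37 rising and 0 falling (10 and 0 adjusted over the list alone; adjusted p = 1.58e-07, adjusted p = 0.286 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.12 with 0 of 33 called (0 adjusted over the list alone; adjusted p = 0.00351, adjusted p = 0.0966 with an estimated correlation). Ribosome biogenesis genes (median -0.15, 0 of 25 higher and 1 lower, 0 and 4 adjusted over the list alone) had adjusted p = 0.00125, adjusted p = 0.286 with an estimated correlation. Cholesterol biosynthesis genes (-0.18, 0 of 18 higher and 1 lower, the same adjusted over the list alone) had adjusted p = 0.0370, adjusted p = 0.341 with an estimated correlation. Zinc finger genes (-0.096, 1 of 277 higher and 1 lower, the same adjusted over the list alone) had adjusted p = 0.00351, adjusted p = 0.292 with an estimated correlation. In OCI-Ly7, SH2B2 rose by 1.84 ± 0.28, DDX59 by 1.84 ± 0.48 and NCF1, a subunit of the phagocyte oxidase, by 1.73 ± 0.19. ZNF121 fell by 1.71 ± 0.15 and CBX6, a Polycomb protein gene, by 1.67 ± 0.22, and CLK3 by 1.71 ± 0.19, though the other CLK3 probe moved the other way. In U2932 130 genes were higher and 89 lower, against 1076 and 1222 with the spread from the 6 arrays compared, 12 and 8 under median scaling and 221 and 182 without background correction. With each array left out in turn they were 33 to 56 and 19 to 26. In OCI-Ly7 1163 were higher and 1371 lower, against 251 and 373 with the spread from the 6 arrays compared, 637 and 83 under median scaling, and 738 to 1466 and 851 to 1766 with each array left out in turn. In OCI-Ly7 0 lists were called by camera (3 at an unadjusted p under 0.05), 0 with an estimated correlation and 3 by fry.

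The lines differed in DMSO in many B cell genes, which also served as a check of the labels. BCL2, the anti-apoptotic gene, was at least 65.8-fold higher in U2932 than in OCI-Ly7, where it was in the background on all 6 DMSO arrays. CYB5R2 was at least 11.7-fold higher and BATF, an AP-1 factor of activated lymphocytes, at least 2.70-fold higher, and TNFRSF13B (TACI) was higher by 3.61 ± 0.10 and IRF4 by 1.01 ± 0.07. Markers of the activated B cell-like subtype were higher in U2932 in 11 of 16 members and lower in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00740, adjusted p = 0.0831 with an estimated correlation). FOXP1 was higher by 0.53 ± 0.08, though 1 of its 3 probes moved the other way, and FUT8 was lower by -1.20 ± 0.20.

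Markers of the germinal centre subtype went both ways between the lines in DMSO, 6 higher and 6 lower of 13. MME was lower in U2932 (-1.99 ± 0.11), as were GCSAM (-1.81 ± 0.11), STAP1 (-1.58 ± 0.17) and MYBL1 (-1.37 ± 0.15). SERPINA9 and LMO2 were in the background in OCI-Ly7 and at least 21.3-fold and 2.53-fold higher in U2932. NF-kB targets were higher in U2932 in 14 of 20 members and lower in 2, the same adjusted over the list alone (adjusted p = 0.00156, adjusted p = 0.304 with an estimated correlation). Interferon response genes were lower in 12 of 20 and higher in 3, the same adjusted over the list alone (adjusted p = 0.0183, adjusted p = 0.0831 with an estimated correlation), 9 and 9 with quantiles within each line and 10 and 7 under median scaling. Their median was -0.46, and -0.11 and -0.34 in these alternatives; relative to all genes it was -0.48, -0.71 and -0.87. Mitosis genes were lower in 29 of 37 and higher in 2, the same adjusted over the list alone (adjusted p = 0.000342, adjusted p = 0.472 with an estimated correlation), with a median of -0.51 that was 0.11 under median scaling (5 lower, 9 higher) and 0.19 with quantiles within each line (9 lower, 18 higher). Relative to all genes the mitosis median was -0.53, -0.43 and -0.40. Glycolysis and hypoxia genes were lower in 20 of 31 and higher in 7, the same adjusted over the list alone (median -0.70, adjusted p = 0.0200, adjusted p = 0.700 with an estimated correlation), 13 and 12 with quantiles within each line and 14 and 11 under median scaling, with a median of -0.21 in both. Relative to all genes the median was -0.72, -0.81 and -0.75. Of all genes, 3441 were higher in U2932 and 3219 lower; under median scaling 5800 and 1212 (median of all genes 0.54) and with quantiles within each line 6667 and 1334 (median 0.60). Each line has its own chip in DMSO, so line and chip cannot be told apart.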

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

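The tests of chip position, of the lone chip and of the small RNAs were chosen only after the result was seen. The lists, the comparisons, the splits of the arrays and the tests of array brightness were set before the data were examined.

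The trabectedin response differed between the 2 lines by a test of the difference itself, the interaction of line and treatment. At 8 h, 1451 genes responded higher in U2932 and 2223 lower, and 336 and 598 with chip position as a covariate. Treated arrays of 8 h lay early on the chip in U2932 and late in OCI-Ly7, so a trend along the chip would enter this difference. The slope along the chip was estimated from small steps within groups and carried over the whole chip. This widens the standard errors by design, so calls would be lost without any trend. CPLX4 (4.25), UBASH3B (3.67), SORBS2 (3.22), IDI2 (3.02) and SIPA1L2 (2.69) had the highest fitted log2 differences by the rule for named genes. ZBTB7C (-4.18), SPIRE1 (-3.74), WWC1 (-3.58), IGF2BP2 (-3.36) and NCALD (-3.31) had the lowest. CPLX4, ZBTB7C, SPIRE1, WWC1, IGF2BP2 and NCALD were in the background in OCI-Ly7 on all 8 h arrays, and UBASH3B and SIPA1L2 in U2932. For 7 of these 8 genes the difference follows from which line expresses the gene in DMSO; CPLX4 was in the background in DMSO in both lines and rose in U2932 alone. IDI2 was in the background in DMSO in both lines, and SORBS2 in U2932 DMSO and in treated OCI-Ly7. Where a group is in the background, a fitted difference gives no size, and the order of such genes is not known.

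At 24 h, 2405 genes responded higher in U2932 and 3837 lower. RNA18SN5 (6.69), GJB2 (4.03), CPLX4 (3.87), UPP1 (3.76) and SNORD46 (3.70) were highest, and SGPP2 (-5.01), ZNF215 (-4.80), SCAMP1 (-4.27), ZBTB7C (-4.21) and HPCAL1 (-4.12) lowest. GJB2, CPLX4, UPP1, SGPP2 and ZBTB7C were in the background in OCI-Ly7 on all 24 h arrays, and SGPP2, ZNF215, SCAMP1 and HPCAL1 on the treated U2932 arrays, so their values are no sizes either; 1 of the 3 SCAMP1 probes differed the other way.

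List medians of the line difference at 8 h were 0.41 for ATF4 targets (-0.21 under median scaling, 0.38 above all genes), 0.73 for histones, 0.63 for immediate early transcripts and 0.65 for myeloid markers. At 24 h they were -0.99 for NF-kB targets, 0.91 for ATF4 targets, 1.14 for histones, -1.06 for mitosis, 0.35 for immediate early transcripts, 0.45 for ribosome biogenesis and 0.98 for myeloid markers. With an estimated correlation between genes, 0 of these lists were called.

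The response also differed between the times by the interaction of time and treatment. In U2932, 1562 genes were higher at 24 h and 2574 lower. GJB2 (3.49), LINC00115 (2.94), SNORD71 (2.77), MEX3B (2.61) and SNORD37 (2.60) were highest, and MGST2 (-3.23), IKZF3 (-3.22), MIR3142HG (-3.09), NAPSA (-3.05) and ACOT13 (-2.95) lowest. GJB2, LINC00115, SNORD71 and SNORD37 were in the background in all groups but the treated one of 24 h. MGST2, IKZF3, MIR3142HG and ACOT13 were in the background on the treated arrays of 24 h, so these are no sizes. In OCI-Ly7, 2319 were higher and 2068 lower. ENO3 (3.11), DPP7 (3.06, with 2 of its 4 probes the other way), JSRP1 (2.94), HPCAL1 (2.93) and ULK1 (2.84) were highest, and PRKCB (-3.24), RNA18SN5 (-3.19), STX8 (-3.18), MAZ (-3.07) and RPL36A (-2.96) lowest.

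List medians of the time difference in U2932 were -0.68 for NF-kB targets, 0.76 for histones, -0.81 for B cell receptor signalling, -1.11 for germinal centre markers and -0.54 for plasma cell differentiation. With genes in the background at their bound, the NF-kB median of the trabectedin effect in U2932 was 0.19 at 8 h and 0 at 24 h. Immediate early transcripts had 0.37 (-0.13 under median scaling, 0.28 above all genes) and zinc finger genes 0.24 (-0.044 under median scaling, 0.37 above all genes). With an estimated correlation between genes, 0 of these lists were called (for plasma cell differentiation adjusted p = 0.0363, adjusted p = 0.174 with an estimated correlation). In OCI-Ly7 they were 0.58 for NF-kB targets and 0.95 for cytokines and chemokines. Under median scaling 3 others changed sign: mitosis from 0.52 to -0.40, immediate early transcripts from 0.53 to -0.37 and zinc finger genes from 0.28 to -0.50, which stayed above all genes by 0.29, 0.32 and 0.19. Here too, 0 lists were called with an estimated correlation.

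Other splits of the arrays were fitted for each comparison. For trabectedin against DMSO, 10 splits of 6 arrays are too few for a share under 0.05; the real split, 1 of 10 in each case, called 6676, 7749, 6009 and 6136 genes (U2932 at 8 h and 24 h, OCI-Ly7 at 8 h and 24 h), and the highest of the others 0, 0, 2 and 180. The same limit holds for DMSO over time, with 219 against 0 in U2932 and 2534 against 712 in OCI-Ly7. For the line difference, 9 of 100 splits at 8 h and 8 at 24 h called as many genes as the real 3674 and 6242, the highest of the others being 7310 and 7849. For the time difference, 13 of 100 did in U2932 and 5 in OCI-Ly7, with real counts of 4136 and 4387 and the highest of the others at 7014 and 6703. By these shares alone chance was not excluded for the 4 differences. All other splits as large (8, 7, 12 and 4) kept the treated and DMSO arrays of 1 line or time apart as in the real split, a structure of the samples. Splits that mixed them in both called at most 0, 0, 0 and 1 genes. For the lines in DMSO, 1 of 100 splits, the real one, called as many as 6660 genes, the highest other being 4522. That share is under 0.05 and the smallest that 100 splits allow, which argues against a chance division of these arrays only. All other splits mixed the lines within groups, so a line difference widened their spread, and they were not arranged by time. The arrays of each line repeat 1 line, so the share does not speak for other lines. A difference between chips would give the same result, since each line has its own chip in DMSO.

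The first pattern weighed is the response that the lines shared at 8 h. Treated arrays took early chip positions in U2932 and late ones in OCI-Ly7, so a trend along the chip predicts opposite changes, but the correlation between the lines stayed at 0.756 or higher with each of 12 arrays left out. Array brightness predicted at most 3.39% of the response in U2932 at 8 h and 5.63% at 24 h (upper 95% limits), and 1.63% and 0.617% in OCI-Ly7. The lower limits were -1.88%, -3.74%, -4.52% and -12.1%, where a negative value runs against the response. These values argue against chip position as the whole cause of the shared response at 8 h. The brightness slope came from differences between replicates after quantile normalisation and was carried over to differences between groups. It argues only against a brightness effect like that between replicates as the whole cause. A transcriptional effect of the drug may explain the shared part at 8 h, as a hypothesis found on the same data.

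The second pattern is that mitosis genes fell in U2932 at both times and in OCI-Ly7 at 8 h, but not in OCI-Ly7 at 24 h, where under median scaling they fell, with a median of -0.86, 0.11 below all genes. By the same kind of slope, brightness predicted a shift of the mitosis genes of at most 0.258 in size. Their line difference was -1.06 (-1.27 under median scaling). This argues against a brightness effect like that between replicates as the whole cause. The treated OCI-Ly7 arrays of 24 h lay alone on a chip, no group lay on both chips, and for their median of 0.0494 chip and treatment cannot be told apart; whether mitosis genes fell there also depends on the scaling. A difference in how the lines arrest or recover also stays open and was not tested.

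The third pattern is a rise of small non-coding RNAs, a family of 191 genes defined after the data were seen. In U2932 167 rose and 4 fell at 8 h and 179 rose and 4 fell at 24 h, with medians of 1.24 and 2.11; in OCI-Ly7 105 rose and 8 fell, then 126 rose and 7 fell, with medians of 0.48 and 0.71; the 4 medians were 0.68, 1.16, 0.42 and 0.077 under median scaling and 0.70, 1.33, 0.22 and 0.37 without background correction. With genes in the background at their bound, the 4 medians were 1.12, 1.93, 0.47 and 0.62. A small RNA in the background on all DMSO arrays was tested only if treated arrays detected it. The filter thus favours rises, and the counts of rises may be too high. In U2932 21 of the 191 were in the background in both groups at 8 h and 0 at 24 h. In OCI-Ly7 these were 41 and 23. If messenger RNA were lost from a fixed amount of total RNA, stable transcripts could rise too. Oxidative phosphorylation transcripts, taken as stable, had medians of 0.14, -0.11, 0.045 and 0.076 (0.073, -0.42, 0.26 and -0.65 under median scaling), but whether they were lost themselves was not measured, so a loss of messenger RNA and a true rise cannot be told apart. Whether the probes read the mature forms of these RNAs, of RNA18SN5 or of the histone transcripts was not measured. A change in the forms that were read therefore cannot be told apart from a rise either. Camera with an estimated correlation gave unadjusted p = 0.0436, 0.0254, 0.211 and 0.133.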

How the results depend on the processing

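Normexp without the silent-family probes was chosen after seeing the data, and the other alternatives were set beforehand. Of 22 counts of called genes, 22 stayed within 1.5 times the main count under cyclic loess, the mean of a gene's probes, no filter on dim probes, the trended variance prior, normexp without the silent-family probes and a replicate block. With the replicate block, 585 of 586 named-gene results kept direction and call, and 1 became a call.

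Median scaling moved 16 of the 22 counts, and it does not make the distributions of the arrays alike, as quantile normalisation does. Genes higher numbered 884 in U2932 at 8 h, 1110 at 24 h and 461 in OCI-Ly7 at 24 h, where 5902 were lower. The line difference had 300 higher and 3637 lower at 8 h and 1502 higher at 24 h. The time difference had 221 higher in U2932, and 163 higher and 4379 lower in OCI-Ly7. DMSO over time had 12 higher and 8 lower in U2932 and 637 and 83 in OCI-Ly7, and the lines in DMSO 5800 and 1212. Genes higher in both lines numbered 593 at 8 h and 290 at 24 h, and genes lower in both at 24 h 4748. The median of the mitosis genes in OCI-Ly7 at 24 h went from 0.05 to -0.86. Lists called numbered 8 in U2932 at 8 h, 8 in OCI-Ly7 at 8 h, 10 in OCI-Ly7 at 24 h and 3 for DMSO over time in U2932. Why the number of lists changed was not tested.

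Single genes reversed under median scaling. It lowered the median of all genes in the trabectedin effects named here and raised it between the lines in DMSO, so small changes can reverse. The values are not relative to all genes. In U2932 at 8 h these were NDUFB1 (-0.038) and CD22 (-0.15). In U2932 at 24 h they were IER3 (-0.0014), DNAJB9 (-0.28), CANX (-0.38), HSPB1 (-0.25), DNAJB1 (-0.54), SRXN1 (-0.38), NQO1 (-0.54), KIF23 (-0.40), ERCC2 (-0.43), NDUFA6 (-0.15), BCL10 (-0.070), NFATC1 (-0.70), PIM2 (-0.084) and HLA-C (-0.34). In OCI-Ly7 at 24 h they were HSP90B1 (-0.18), CRELD2 (-0.44), NQO1 (-0.094), SRXN1 (-0.54), MSMO1 (-0.065), CCNE1 (-0.31), XPC (-0.13), FANCE (-0.037), MCL1 (-0.13), RPS9 (-0.042), NDUFA6 (-0.49), NDUFS3 (-0.30) and NFATC1 (-0.32). Between the lines in DMSO they were BCL6 (0.31), RGS13 (0.36) and PIM2 (0.24). Quantiles within each line gave 6667 genes higher and 1334 lower in DMSO, with BCL6 (0.58), RGS13 (0.55) and PIM2 (0.35) reversed. Cyclic loess reversed BCL2 in OCI-Ly7 at 24 h (0.57), where it is in the background. The cause was not tested.

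Of 22 counts of genes that changed by at least 1 on the log2 scale, 22 moved by over 1.5 times without background correction and 22 with the authors' deposited values. With offset 50, 13 moved, under median scaling 16, and among genes detected on all arrays compared 13. In U2932 at 8 h offset 50 gave 634 higher and 1312 lower, against 1000 and 1835. Without background correction, the medians of the lists called in the trabectedin effects were nearer 0, such as 0.66 against 1.71 for myeloid markers in U2932 at 8 h.

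For DMSO over time in U2932, no background correction gave 221 higher and 182 lower, the authors' deposited values 221 and 182, offset 50 gave 144 lower, and the fit without the lone chip 204 and 150. With only the arrays compared in the fit the counts were 1076 and 1222 in U2932 and 251 and 373 in OCI-Ly7; by construction each line then has its own spread. The cause of the others was not tested.

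Among genes detected on all arrays compared, where fewer genes are tested, 2068 were lower in U2932 at 8 h and 1856 at 24 h. Of 49 results for called lists, 20 lost their call. The line difference had 859 higher, 1309 lower and 1 list called at 8 h, and 1383, 1720 and 3 lists at 24 h. The time difference had 1314 lower and 3 lists in U2932 and 2 lists in OCI-Ly7, and the lines in DMSO 1 list. Genes lower in both lines numbered 1285 at 8 h and 1007 at 24 h. ELMO1 in OCI-Ly7 at 24 h reversed (0.13), since another probe then stands for the gene. With no filter on dim probes, lists called were 6 in OCI-Ly7 at 8 h, 12 for the line difference at 24 h, 14 and 8 for the time difference in U2932 and OCI-Ly7, and 1 for DMSO over time in OCI-Ly7.

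With the mean of a gene's probes, whose probes disagree, KIF23 reversed in U2932 at 8 h (-0.17) and 24 h (-0.18) and in OCI-Ly7 at 8 h (-0.28). NFATC1 did so in U2932 (-0.51) and OCI-Ly7 (-0.42) at 24 h, GCLM in OCI-Ly7 at 24 h (0.24) and FOXP1 between the lines in DMSO (-0.035). With chip position as a covariate, the line difference at 8 h had 336 higher and 598 lower. The time difference in OCI-Ly7 had 1463 and 1254, and OCI-Ly7 at 8 h had 5 lists called. Of 586 named-gene results 21 lost their call and 0 reversed, and of 54 results for called lists 3 lost their call. The covariate widens the standard errors where groups differ in position, so lost calls cannot tell a trend along the chip from lower precision. The cause was not tested. Genes with a log2 change of 1 or more in both lines numbered 406 higher and 907 lower at 8 h and 653 and 944 at 24 h, by the stricter threshold.

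With an estimated correlation, 0 lists were called in each of the 11 comparisons. Fry, whose question does not set the list against other genes, called 25, 28, 19 and 21 in the 4 trabectedin effects, 13 and 22 for the line differences, 22 and 16 for the time differences, 8 and 3 for DMSO over time (U2932, OCI-Ly7) and 26 for the lines in DMSO.

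Leaving out each array in turn reversed 0 named genes. Of 3930 named-gene results, 59 lost their call and 3 became calls, and of 492 results for called lists 23 lost their call. DMSO over time in U2932 then had 33 to 56 genes higher and 19 to 26 lower, whichever array was left out. In OCI-Ly7 it had 738 to 1466 higher, 738 without DMSO 8 h replicate 1, and 851 to 1766 lower, 851 without DMSO 24 h replicate 3; lists called were 0 to 1, 1 without DMSO 8 h replicate 2. Lists of the line difference at 24 h were 4 to 8, 4 without OCI-Ly7 DMSO 24 h replicate 1. Lists of the time difference in OCI-Ly7 were 1 to 6, 1 without trabectedin 24 h replicate 2 and 3 without DMSO 8 h replicate 2. Signal over background limits genes near the threshold.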

Other observations

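The test of neighbouring genes was chosen only after the result was seen, and the test of fragile-site genes before.

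Several lists of the DNA damage and stress response were not called by camera in the 4 trabectedin effects. Of 19 p53 targets, 8 rose and 4 fell in U2932 at 8 h, 10 and 6 at 24 h, and in OCI-Ly7 6 and 4, then 9 and 4. Median scaling lowered the median of all genes in U2932 and in OCI-Ly7 at 24 h. Under it the p53 counts were 3 and 6, 4 and 9, 4 and 3, and 1 and 9. Relative to all genes, the p53 median in U2932 was 0.29 at 8 h and 0.49 at 24 h, and 0.32 and 0.48 under median scaling. In OCI-Ly7 the p53 median was -0.073 at 8 h and 0.20 at 24 h, where all genes had medians of -0.0033 and 0.0028. CDKN1A (p21) rose by 1.41 ± 0.12 in U2932 at 8 h (n = 3), and RRM2B fell by 1.09 ± 0.13. Of 25 nucleotide excision repair genes, 4 rose and 11 fell, 6 and 17, 8 and 8, and 8 and 7, and under median scaling 0 and 17, 0 and 20, 4 and 6, and 1 and 17. MNAT1, a subunit of the CDK-activating kinase, was in the background on all treated arrays of U2932 and at least 3.95-fold lower at 8 h and 2.91-fold at 24 h. In OCI-Ly7 at 8 h MNAT1 fell by 2.49 ± 0.15. Of 20 pro-apoptotic genes, 11 rose and 5 fell, 10 and 6, 7 and 3, and 8 and 3, and under median scaling 3 and 5, 3 and 12, 6 and 2, and 1 and 12. Their median in U2932 lay above that of all genes by 0.33 at 8 h and 0.56 at 24 h, and by 0.10 and 0.18 under median scaling. Cytochrome c (CYCS) rose by 2.41 ± 0.14 in U2932 at 8 h.

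Host genes of common fragile sites, most of them very long, may be lost first when a drug blocks elongation. Of 26 listed genes 7 were tested (AUTS2, DLG2, DMD, DPYD, IMMP2L, MAD1L1 and NBEA), and 6, 7, 5 and 6 of them fell in the 4 effects (U2932 at 8 h and 24 h, OCI-Ly7 at 8 h and 24 h), with 0 rising. Their medians were -1.56, -1.66, -0.47 and -1.39. Among 10000 random lists matched on expression these lay at percentiles 0.44, 1.23, 15.17 and 0.03. The prediction of the lowest 5% held in 3 effects and not in OCI-Ly7 at 8 h (15.17), so the test leaves it open, and gene length itself was not measured.

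Genes first detected after trabectedin could be read through from an expressed neighbour. Of 251, 215, 157 and 144 such genes in the 4 effects, 30.3%, 32.6%, 22.3% and 26.4% had a neighbour in the top 25% of genes detected in DMSO, against 15.3%, 15.6%, 15.5% and 14.5% of genes that stayed undetected. Without the 5 genes that prompted the test, the odds ratios (Fisher's exact test) were 2.32, 2.498, 1.486 and 1.95. The lowest, in OCI-Ly7 at 8 h, had a 95% interval of 0.976 to 2.21, which includes 1. Neighbours were the genes on either side by start position among genes on the array, and strand and distance were not used. The odds ratios therefore cannot tell read-through from a higher density of genes around genes that become detectable. The test leaves this hypothesis open.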
